A study of Mus musculus with 2 samples.

How the data were processed

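CTCF ChIP-seq was measured in midbrain tissue of B6NCrl mice at postnatal day 0, in 2 replicates of 1 group. Sex was not collected, per the labels, and both replicates carry the same biosample and donor record. The authors deposited 5 peak lists in narrowPeak format on assembly mm10, per the deposited text notes. Of these, 1 was called on each replicate's alignments with a control alignment and 1 on both replicates together. A further 2, called optimal and conservative, were thresholded by the irreproducible discovery rate (IDR), which compares peak ranks between 2 sets of peaks. Which sets were compared for each list is left open here. An optimal peak therefore need not have passed a comparison of the 2 replicates. The peak caller, its version, the aligner, the read length, the read depth and the IDR threshold are not given in the sources used here. Because depth is unknown, a gene or region without a listed peak is one where none was listed, not one shown to lack CTCF.

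Each deposited list gives a signal value per peak, whose scale is not stated in the sources used here and which was not made comparable between libraries by any step recorded in the deposited notes. The signal of an optimal peak was that of the list called on both replicates together, within 0.005 and at the same summit, for all 68603 peaks. A deposited -log10 q value is capped at the highest value of each list, 5.18 in the optimal list, which 96.05% of its peaks carry, so it could not rank peaks. The deposited score column runs up to a fixed ceiling and was not used to rank either. The conservative list held 65493 peaks, of which 59642 shared a summit with the optimal list. The median signal was 97.0 for shared peaks, 26.4 for 8961 peaks in the optimal list alone and 26.0 for 5851 peaks in the conservative list alone, so the lists differ in weak peaks. Both of these lists were thresholded by IDR, which limits what the comparison of replicates within the optimal list can show.

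Coordinates are 1-based on mm10. Sequence and repeat masking came from GRCm38.p6, of the same build, and gene starts from GENCODE vM21. Peaks on chromosomes 1 to 19 and X were analysed, and 13 on scaffolds were left out. Which comparisons, gene lists, loci, tests and most alternatives to use was fixed before the data were examined. The gene lists held 566 symbols in 26 lists, of which 565 were matched to the annotation and Pcdha10 was not. Of the loci, 28 were used, and an olfactory receptor cluster was not used because the genes meant to bound it lie on different chromosomes.

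Replicate matching took as many of each replicate's highest-signal peaks as the optimal list holds and counted summits within 100 bp of a summit in the other list, against 20 sets of random positions. Signal was compared by rank, and by the log2 ratio about its median, across peaks of the optimal list found in both replicate lists. A CTCF weight matrix of 20 bp was learned from the 2000 strongest peaks of odd-numbered chromosomes and X and used on even-numbered ones, and the reverse, so no peak was scored by a matrix it helped to make. A match needed a per-position p of 1.00e-05 within 50 bp of the summit. Flanking windows 1 kb to each side were the background. Locations were assigned in the order promoter (within 1 kb of any annotated transcript start), exon, intron and intergenic, and compared with 100 random placements outside assembly gaps. Peaks are not independent replicates, so differences were tested across the 19 autosomes as blocks with an exact two-sided sign-flip test, whose smallest p is 3.81e-06. Gene lists were tested with Fisher's exact test against all other protein-coding genes (all other annotated genes for the imprinted list), with Benjamini-Hochberg adjustment over the 26 lists and a threshold of 0.05. Strands were shuffled within chromosomes 100000 times. Loci were compared with 10000 random autosomal windows. Intervals are 95% Wilson intervals.

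Named genes and peaks followed a rule. These were the 10 peaks of highest signal, up to 4 members of each list with the strongest promoter peak and up to 2 without one, all loci, and the 5 peaks most discordant between replicates in each direction. Only some of the list members and loci so chosen are printed, and a few of them are not reported here. The peaks at 37217488 and 37218432 on chromosome 18 were chosen after their values were seen.

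Alternatives changed 1 choice at a time, with exceptions. GC matching replaced the test along with the comparison genes. The imprinted comparison among protein-coding genes changed both the members and the background. Leaving out a replicate also dropped the IDR threshold, the call on both replicates together and its signal values. A result that changed there cannot be put down to the missing replicate alone. The alternatives were the conservative list, the stronger 50% of the optimal list, each replicate left out (using the other's own strongest peaks), motif thresholds of 1.00e-04 and 1.00e-06, a window of 100 bp, flanks 3 kb away, and promoters of 500 bp and 5 kb. Further ones were protein-coding genes only, the outermost gene start only, random lists matched on promoter GC content, and for replicate matching any overlap of 1 bp, 50% reciprocal overlap, the highest 10000 peaks and the whole lists. The distance between motif sites by orientation, the weaker 50% of the optimal list and the imprinted list's protein-coding members against other protein-coding genes were added after seeing the data.

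The statistics were tested on simulated data. The motif search found 99.2% of planted sites and called 0.62% of the windows without one, of 2000 windows. Planted sites were drawn from a sharpened form of the matrix that starts the search. The recovery therefore does not give the sensitivity for real sites that match less well. The sign-flip test gave p under 0.05 in 52 of 1000 simulated sets without a difference and in 984 of 1000 with a mean difference of 1 SD. The list test called 1 of 200 random lists of 20 genes and 50 of 50 planted ones. The strand permutation gave p under 0.05 in 27 of 400 sets with random strands and 400 of 400 with planted order. Summit matching found 70.6% where 69.6% was planted. Analyses used Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3, Numba 0.67.0 and matplotlib 3.10.9.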

Results

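The series holds CTCF chromatin immunoprecipitation followed by sequencing (ChIP-seq) from the midbrain of B6NCrl mice on postnatal day 0. CTCF is a zinc finger protein that binds a long directional DNA motif and, with the cohesin ring complex, anchors chromatin loops and domain borders. There was 1 group of 2 replicates, with a control alignment used for peak calling. Both replicates were listed under the same tissue sample and donor record, so the spread between them may be technical only. With 1 group there was no comparison between conditions, and the design leaves 2 kinds of question, how well the replicates match and where CTCF peaks lie in newborn midbrain. The optimal list, 1 of the 2 deposited lists thresholded by IDR, held 68603 peaks on assembly mm10. Of these 68590 lay on chromosomes 1 to 19 and X. Its peaks had a median width of 310.0 bp and a median signal value of 76.5, with a range of 6.81 to 691. Each replicate's own list held 300000 peaks, a round number that includes many weak ones. Read depth is not given in the lists, so the precision stated for shares is the 95% Wilson interval over peaks. Such intervals cover counting error only. Signal values are the authors' own, on a scale not given in the sources used here. They were used to describe, rank and compare peaks within a list. Between replicates they were compared by rank and by a log2 ratio, whose median includes any difference of scale between the libraries.

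The replicates were compared first, as the strength of every later statement rests on them. Of the 68591 highest-signal peaks of replicate 1, 58837 (85.8%, 95% interval 85.5 to 86.0) had a summit of replicate 2's equally long list within 100 bp. Random positions on the same chromosomes gave 0.569% (0.510 to 0.640 over 20 draws). Matching depended on signal. In the strongest 10% of replicate 1's peaks 99.985% were matched, against 41.0% in the weakest 10%, of which 85.7% had a match in replicate 2's whole list. Signal was found in both replicate lists for 67101 optimal peaks (97.8%), and across these peaks, which are not independent, Spearman's rho was 0.948 (SD 0.00476 over 19 autosomes, range 0.938 to 0.954). The log2 ratio of replicate 1 to replicate 2 signal had a median of 0.30 and an SD of 0.46 over peaks, and 94.8% of peaks lay within 2-fold of that median.

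**Figure D1:**
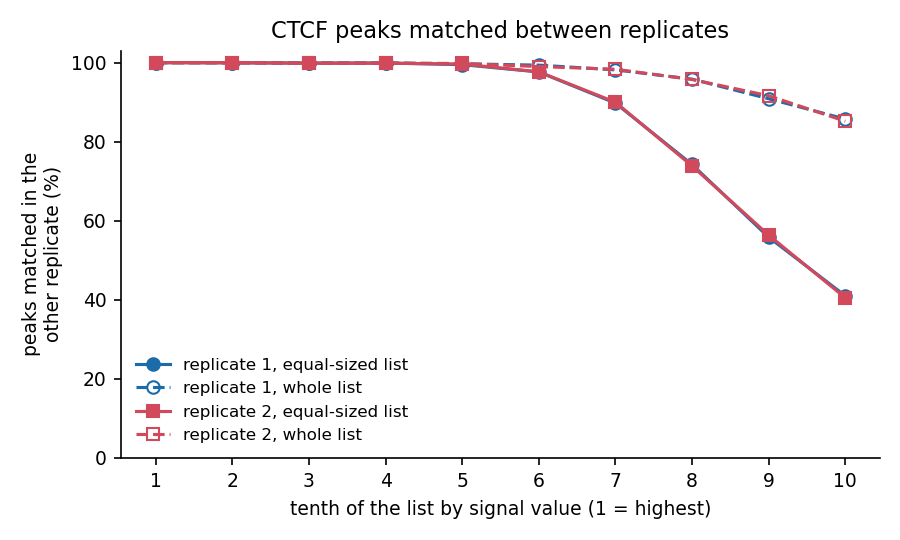
Percent of each replicate's peaks with a summit of the other replicate within 100 bp (vertical axis), by signal group of 10% of the peaks from strongest to weakest (horizontal axis), against equally long lists (solid lines) and whole lists (dashed lines). Matching is above 99% in the first 5 groups and falls to 41.0% and 40.5% in the weakest group when equally long lists are compared.

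A few peaks ranked far apart in the replicates. The largest excess in replicate 1 was 108 bp upstream of a start of Papss1, which encodes an enzyme making the sulfate donor of the cell. Its signal percentile among optimal peaks was 56.4 in replicate 1 and 1.61 in replicate 2. Next came peaks in an intron of Cntn2 (56.8 against 4.73), at Dab1, an adaptor of reelin signalling in neuron migration (53.0 against 1.76), in Slc6a6, the taurine transporter gene (53.4 against 3.18), and in Olfr750 (49.99 against 2.13). The reverse was seen 248 bp upstream of Coq10b (7.29 in replicate 1 and 56.4 in replicate 2). The same held for the starts of Kif13a (6.34 against 54.2) and Rnls (4.11 against 51.4), for a peak 65120 bp from the pseudogene Gm5259 (1.89 against 48.8) and for one in an intron of Abhd12 (1.43 against 46.6). Of these 10 peaks, 3 held a CTCF motif, those at Cntn2, Rnls and near Gm5259.

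At a per-position p of 1e-05, a match to the CTCF motif lay within 50 bp of the summit in 44255 of 68590 peaks (64.5%, interval 64.2 to 64.9; SD 1.60 over 19 autosomes), against 1.31% of windows 1 kb to either side. The 49.3-fold difference was present on 19 of 19 autosomes (exact sign-flip test, two-sided, p = 3.81e-06, the smallest this test can give). The share was 83.0% at a looser p of 1e-04 (14.2-fold over the flanks) and 38.5% at a stricter one of 1e-06 (116-fold). At the p of 1e-05 the motif was found at 93.3% of the strongest 10% of peaks and at 36.3% of the weakest 10%. Its centre lay a median of 5 bp from the summit, and 92.6% of sites were centred within 20 bp. Peaks with the motif had a median signal of 117, against 46.3 for peaks without it. The median signal percentile was 29.2 points higher with the motif (SD 1.83 over autosomes; higher on 19 of 19; exact sign-flip test, p = 3.81e-06). The matrix was learned from the strongest peaks of other chromosomes, and one learned from weaker peaks was not tried. How much of the difference by signal comes from that choice was not measured.

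The strongest peaks give examples with their sequence in the mm10 assembly. The highest signal, 691 (353 in replicate 1 and 339 in replicate 2), belonged to a peak on chromosome 2 at 32912432 to 32912831, in an intron of Fam129b, with the motif CAACCACTAGGTGTCGCCAT at 32912628 to 32912647 on the minus strand. The next, signal 682, lay between genes on chromosome 5 at 130853335 to 130853759, with CTACCGGCAGGGGGCGCTCG at 130853527 to 130853546, minus strand. An intergenic peak 13517 bp upstream of Rbm19 (chromosome 5, 120102760 to 120103172, signal 667) held CGGCCACCAGGGGGCGCACA at 120102927 to 120102946, minus strand. An intron of Pink1, which encodes a mitochondrial kinase mutated in inherited parkinsonism, held a peak of signal 647 (chromosome 4, 138319523 to 138319938) with TTACCACTAGGTGGCGCTAC at 138319715 to 138319734, plus strand. Other intergenic peaks among the strongest lay near Kcnk18, a potassium channel gene (666), Glrx3 (648), Slc17a9, the vesicular nucleotide transporter gene (645), Stmn1, which encodes the microtubule regulator stathmin (638), and the pseudogene Gm47714 (635). A peak in an intron of Col18a1, a collagen gene, had a signal of 637. All 10 of the strongest peaks held a motif match and lay more than 1 kb from any annotated start.

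**Figure D2:**
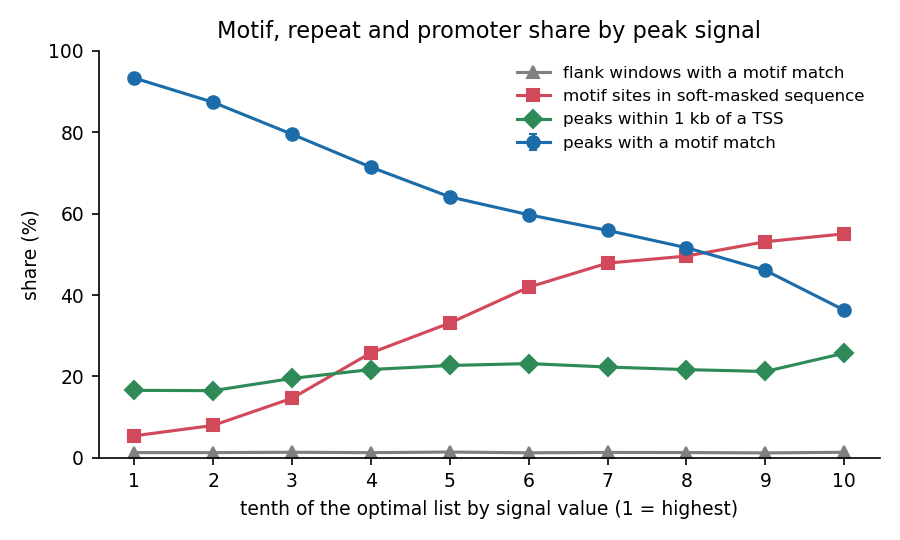
Percent of peaks with a CTCF motif, at promoters, and of motif sites in soft-masked repeats (vertical axis, percent, 95% Wilson intervals for the motif smaller than the symbols), with flanking windows in grey, by signal group of 10% of the peaks from strongest to weakest (horizontal axis). The motif share falls from 93.3% to 36.3% while the share of motif sites in repeats rises from 5.41% to 55.0%.

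Peaks were concentrated at promoters. Summits lay within 1 kb of an annotated transcription start in 14473 cases (21.1%, interval 20.8 to 21.4), against 6.35% of random placements (6.12 to 6.56 over 100 placements), a ratio of 3.32. Exons held 4.97% against 3.42% at random, and intergenic sequence held less than random, 33.7% against 49.97%. Each of these differences had one direction on 19 of 19 autosomes (exact sign-flip tests, two-sided, p = 3.81e-06 for each). Introns held 40.2% of summits and 40.3% of random positions, higher on 10 of 19 autosomes, and this difference did not pass the exact test (p = 0.898). Promoter peaks were weaker than the others. Their median signal was 67.6 against 79.4 for peaks farther from a start, a difference of -5.04 percentile points (SD 2.71), and promoters were higher on 1 of 19 autosomes (exact sign-flip test, p = 7.63e-06). With promoters defined as 5 kb either side of a start the difference was -1.26 points and no longer passed the exact test (p = 0.0505; range over 6 alternatives 3.81e-06 to 0.0505). Of the 14473 promoter peaks 6379 held a motif, against 44255 of all 68590 peaks, and peaks with a motif had higher signal. The signal difference was not tested among peaks of like motif status.

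**Figure D3:**
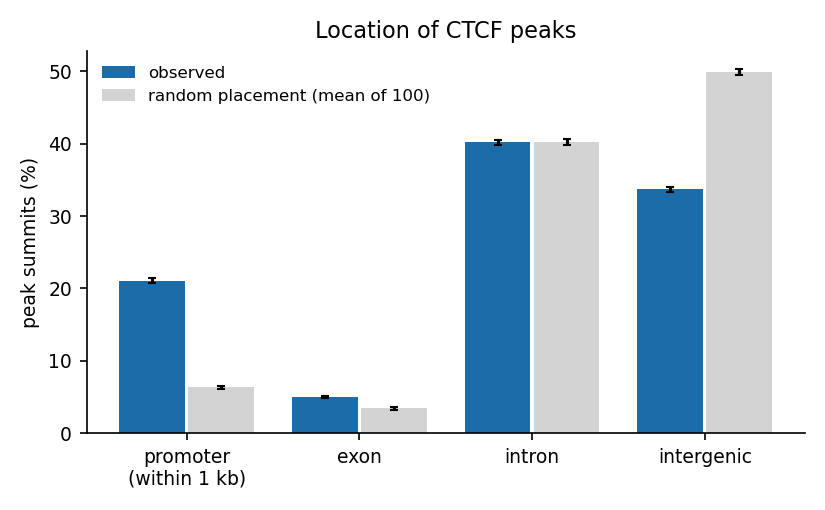
Percent of peak summits (bars with 95% Wilson intervals) and of random placements (mean of 100, with lowest and highest) in promoters, exons, introns and intergenic sequence (vertical axis, percent). Promoters hold 21.1% of summits against 6.35% of random placements, and intergenic sequence 33.7% against 49.97%.

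Among protein-coding genes, 9431 of 21755 (43.4%) had a peak within 1 kb of a start. Of 26 gene lists, 12 differed from other genes (Fisher's exact test, two-sided, Benjamini-Hochberg over the lists), 8 above and 4 below. The number that differed was 13 without replicate 1 and 8 without replicate 2. The clustered protocadherins, neuronal adhesion genes whose alternative promoters are chosen cell by cell, were among the highest shares. A promoter peak was present at 12 of 13 alpha genes (92.3%, adjusted exact p = 0.0015), 19 of 22 beta genes (86.4%, adjusted exact p = 5.62e-04) and 18 of 21 gamma genes (85.7%, adjusted exact p = 7.44e-04). Neighbouring promoters in a cluster are not independent, so these p-values are too small. In the stronger 50% of peaks, where 23.1% of other genes had one, all 3 calls were lost. The counts there were 3 of 13 alpha genes (23.1%, adjusted exact p = 1; range over 8 alternatives 1.99e-04 to 1), 1 of 22 beta genes (4.55%, below other genes, 0.212; range 1.52e-05 to 0.212) and 9 of 21 gamma genes (42.9%, 0.212; range 2.29e-05 to 0.212). The strongest alpha promoter peak was at Pcdhac1 (signal 334), followed by Pcdha9 (81.9), Pcdha2 (78.5) and Pcdha12 (74.8), and Pcdha8 had none. Pcdhb10 (94.1), Pcdhb17 (74.2), Pcdhb15 (67.2) and Pcdhb16 (56.3) led the beta genes, and Pcdhb1 and Pcdhb12 were among those without a peak. Pcdhga12 (159), Pcdhgc3 (130.03), Pcdhga11 (125) and Pcdhgb6 (124) led the gamma genes, and Pcdhga9 and Pcdhgc4 were among those without.

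Some housekeeping and activity genes were also above other genes. Ribosomal protein genes had a promoter peak in 56 of 79 cases (70.9%, adjusted exact p = 2.57e-05), with Rplp0 (signal 528), Rps3a1 (495), Rpl26 (483) and Rpl36 (459) the strongest, while Rpl12 and Fau had none. Immediate early genes, which are transcribed within minutes of neuronal activity, had one in 13 of 15 (86.7%, adjusted exact p = 0.0034), including Egr1 (376), Junb (330) and Bdnf, the neurotrophin gene (262), but not Jun or Ier2. The call ended with outermost starts (9 of 15, adjusted exact p = 0.168), in the stronger 50% of peaks (7 of 15, 0.230) and with GC-matched lists (0.0639; range over 8 alternatives 6.03e-04 to 0.230). Imprinted genes, expressed from a single parental allele, had one in 22 of 45, against 23.7% of all other annotated genes (48.9%, adjusted exact p = 0.0015). Its 37 protein-coding members had one in 19 cases (51.4%), against 43.3% of other protein-coding genes, and did not pass (adjusted exact p = 0.423; range over 9 alternatives 1.14e-05 to 0.423). This comparison was chosen after seeing the data. With it, 7 lists passed, as the pan-neuronal, clock, microglia and endothelial lists also no longer did. Blcap (409), Meg3 (301), Grb10 (264) and Gnas (258) led them, and Airn and Calcr had none. Pan-neuronal genes had one in 14 of 20 (adjusted exact p = 0.0479), led by Rbfox3, the gene of the neuronal marker NeuN (492), and Gap43, the growth cone protein gene (459), but not at Dcx or Celf4. That call ended without replicate 1 (12 of 20, adjusted exact p = 0.257) and without replicate 2 (13 of 20, 0.133; range over 8 alternatives 0.00326 to 1). Core clock genes also had one in 14 of 20 (adjusted exact p = 0.0479), with Npas2 (327), Bhlhe40 (313) and Per2 (141) the strongest and none at Clock. The clock call was kept without replicate 1 (14 of 20, adjusted exact p = 0.049). It ended without replicate 2 (13 of 20, adjusted exact p = 0.133, range over 8 alternatives 0.0324 to 0.938).

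Below other genes stood the Hox genes, which pattern the body axis behind the midbrain, with a promoter peak at 7 of 39 (17.9%, adjusted exact p = 0.0034). They too lie in clusters, so this p is too small. Within 5 kb of a start the direction turned, with 25 of 39 (64.1%) against 61.3% of other genes (adjusted exact p = 0.983; range over 8 alternatives 0.00104 to 0.983). The strongest were at Hoxa7 (437), Hoxc5 (268), Hoxb5 (257) and Hoxa10 (168), and Hoxa11 was among those without. Liver genes had one in 1 of 20, at Apob (460; adjusted exact p = 0.0015), with none at Alb or Ahsg. Microglia markers had 2 of 15, among them C1qa (87.2), and endothelial and pericyte markers 2 of 15, at Vwf (346) and Abcc9 (59.6), each with an adjusted exact p of 0.0479. Without replicate 2 the microglia call (2 of 15, adjusted exact p = 0.0515) and the endothelial call (3 of 15, 0.133) ended. Both also ended with the conservative list (adjusted exact p = 0.0665 for each), and both were kept without replicate 1 (0.0426 for each). Of 8 alternatives fixed beforehand, the call was kept in 8 for ribosomal protein genes (adjusted p 1.1e-06 to 0.0016), in 7 for gamma protocadherin genes and in 6 for alpha and beta protocadherins. It was kept in 5 for Hox, immediate early and liver genes, in 2 for pan-neuronal, clock and microglia genes and in 1 for endothelial genes. Matching on promoter GC content ended the imprinted, immediate early, pan-neuronal, clock, microglia, endothelial and liver calls.

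The lists closest to the tissue did not pass the test with promoters of 1 kb. A promoter peak was present at 9 of 28 midbrain patterning genes (32.1%, adjusted exact p = 0.372), among them the hedgehog effectors Gli1 (signal 426) and Gli2 (301), and Foxa1 (136), but not En1 or Barhl1, whose nearest peaks were 1030 bp from a start. Within 5 kb of a start the midbrain list had a peak at 24 of 28 genes (85.7%), above the 61.3% of other genes (adjusted exact p = 0.0279; range over 8 alternatives 0.0279 to 1). Dopaminergic genes had 7 of 20 (35.0%, adjusted exact p = 0.598), with Sox6 (388), Pts, which encodes an enzyme of tetrahydrobiopterin synthesis (318), Kcnj6 (260) and the dopamine neuron regulator Pitx3 (199.6), and none at Aldh1a1 or Calb1. GABAergic genes had 8 of 18 (adjusted exact p = 1), with Gad1, encoding a GABA-synthesising enzyme (252), Gata3 (206) and Tal2 (201). Glutamatergic genes had 4 of 15 (adjusted exact p = 0.386), with Grin2b, an NMDA receptor subunit gene (310.2), and Slc17a6, the vesicular glutamate transporter gene (32.8). Serotonergic and cholinergic genes had 3 of 13 (adjusted exact p = 0.259), Htr1a (355), Tph2, the brain enzyme of serotonin synthesis (218), and Gata3.

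For progenitors the count was 7 of 16 (adjusted exact p = 1), led by Nes, which encodes nestin (296). Astrocyte genes had 8 of 14 (adjusted exact p = 0.519), led by Gfap (473) and the glutamate transporter gene Slc1a2 (152). Without replicate 1 the astrocyte count was 5 of 14, below the share of other genes. Oligodendrocyte lineage genes had 6 of 15 (adjusted exact p = 1), led by Pdgfra (356) and Myrf (286). Cohesin and CTCF cofactor genes had 16 of 25 (64.0%, adjusted exact p = 0.087), led by Stag1 (404), Esco1 (354) and Pds5b (321). Without replicate 1 it was 17 of 25 and passed (adjusted exact p = 0.049; range over 8 alternatives 0.049 to 0.567). The other counts were 3 of 15 for blood (adjusted exact p = 0.137), 5 of 12 for meninges (Col1a1 411; adjusted exact p = 1), 3 of 14 for forebrain (Bcl11b 222; adjusted exact p = 0.182), 4 of 15 for hindbrain (adjusted exact p = 0.386) and 4 of 18 for muscle (Ckm 395; adjusted exact p = 0.164). Blood genes passed, below other genes, without replicate 1 (2 of 15, adjusted exact p = 0.0426) and with promoters of 500 bp (1 of 15, 0.0406; range over 8 alternatives 0.0406 to 0.563). Muscle genes passed, also below, with promoters of 500 bp (1 of 18, adjusted exact p = 0.0182; range over 8 alternatives 0.0182 to 1).

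**Figure D4:**
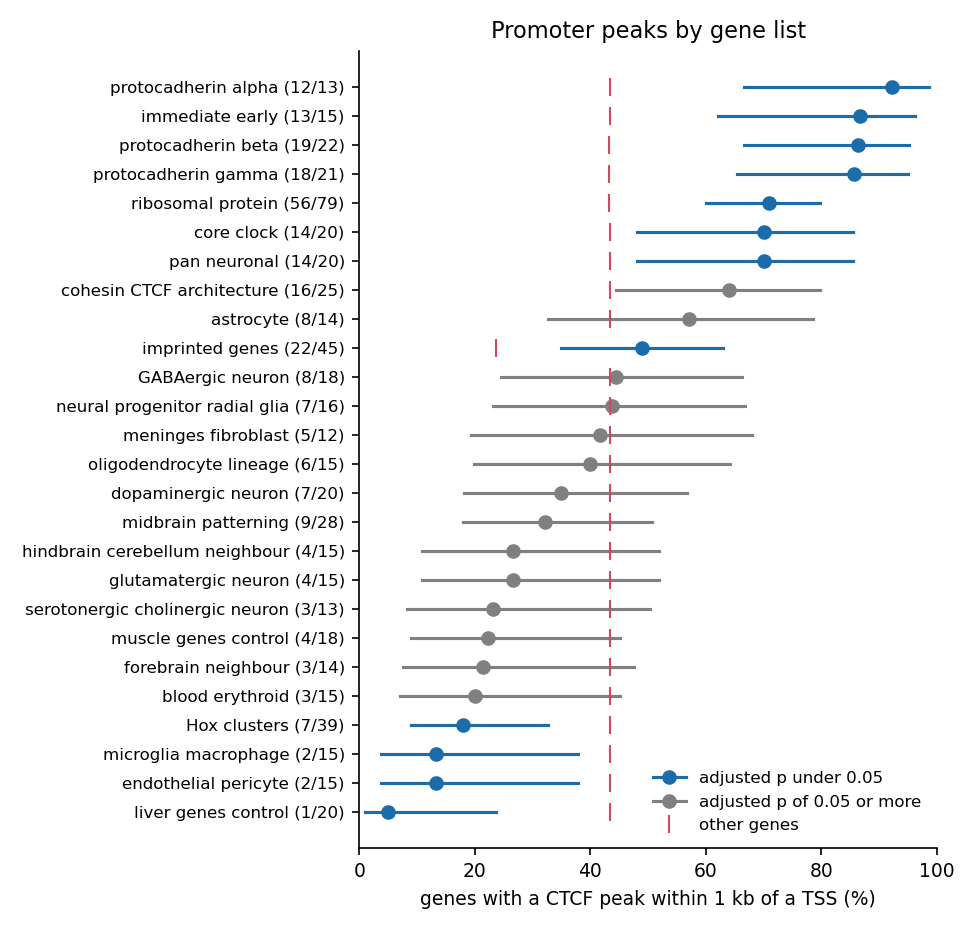
Percent of each list's genes with a peak within 1 kb of a start (points with 95% Wilson intervals, horizontal axis), with counts, beside the share of other protein-coding genes (43.4%) and of all annotated genes for the imprinted list (23.7%). Protocadherin, ribosomal protein, immediate early, pan-neuronal, clock and imprinted genes lie above and Hox, liver, microglia and endothelial genes below.

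At 28 loci of known CTCF or imprinting interest, peaks were counted with 20 kb added on each side and set against 10000 random windows of the same length. No test was made of these values. The windows were autosomal and matched on length but not on genes or gene starts, where peaks were concentrated. Firre and Xist-Tsix lie on X, which held 9.9 peaks per Mb against an autosomal mean of 28.2. Their percentiles therefore do not compare them with other X sequence. The locus of Firre, a long noncoding RNA gene of the X chromosome, held 31 peaks, 19 with a motif, above every random window (percentile 100). Its strongest peak (signal 229.7) lay on X at 50611758 to 50611998 in an intron of Firre. The gamma protocadherin cluster held 28 peaks (percentile 99.6), the Bdnf gene 10 (97.4), the Gnas domain 10 (96.2) and the Dlk1-Meg3 domain 14 (96.1). The strongest Gnas peak (370.5) lay on chromosome 2 at 174312181 to 174312447 in an intron, with TACCCACCAGAGGTCAGCAA at 174312307 to 174312326, plus strand. That of Dlk1-Meg3 (301) lay 776 bp from a start, over an exon of Meg3, on chromosome 12 at 109542918 to 109543170, with AGACCGCTAGGGGGCGCGCG at 109543035 to 109543054, minus strand. That of Bdnf (262) lay 557 bp from a start, over an intron, on chromosome 2 at 109694900 to 109695149, with TGGCCAGAAGAGGGCACCCT at 109695011 to 109695030, minus strand. The immunoglobulin heavy chain variable region, which is rearranged in B cells, held 4 peaks in 2622 kb (percentile 0.93), or 7 (2.18) without replicate 1 and 3 (0.585) without replicate 2. It lies on chromosome 12, which had the lowest autosomal share of motif sites with unique surrounding 36-mers (64.0%). Uniqueness within this region was not measured. Between the 5th and 95th percentiles stood the alpha (20 peaks, 91.6) and beta (19 peaks, 90.5) protocadherin clusters. So did H19-Igf2 (14 peaks, 91.3), Xist-Tsix (8 peaks, 93.8) and the Hox clusters (71.5 to 85.2). Firre and the gamma protocadherins stayed above the 95th percentile under all 4 alternative peak sets, while Gnas (89.6 to 94.6) and Dlk1-Meg3 (88.6 to 92.2) fell below it with the conservative list and with either replicate left out. In the stronger 50% of peaks H19-Igf2 (99.5), Xist-Tsix (97.7) and HoxA (95.3) were above it, and the Peg3 domain was with the conservative list (95.6) and without replicate 2 (95.2). Bdnf (91.6) and Dlk1-Meg3 (86.7) were not in the stronger 50%.

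Motif strand in the protocadherin region had one prevailing direction. On chromosome 18 from 36910184 to 37861873, 69 peaks were found and 32 held a motif, 28 on the forward strand and 4 on the reverse strand. The alpha locus held 12 forward and 1 reverse, the beta locus 15 forward and 0 reverse, and the gamma locus, with 28 peaks, 1 of each. At gene starts a motif lay in the strongest promoter peak of 8 of the 12 alpha genes, 15 of the 19 beta genes and 0 of the 18 gamma genes. At a looser threshold (p of 1e-04) these counts were 11, 19 and 5. Between the alpha and beta clusters, peaks of signal 225 and 312 at 37217488 and 37218432 held reverse motifs. The strongest peak of the region (504) lay beyond the gamma genes at 37852315, in an intron of Diaph1, without a motif match.

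**Figure D5:**
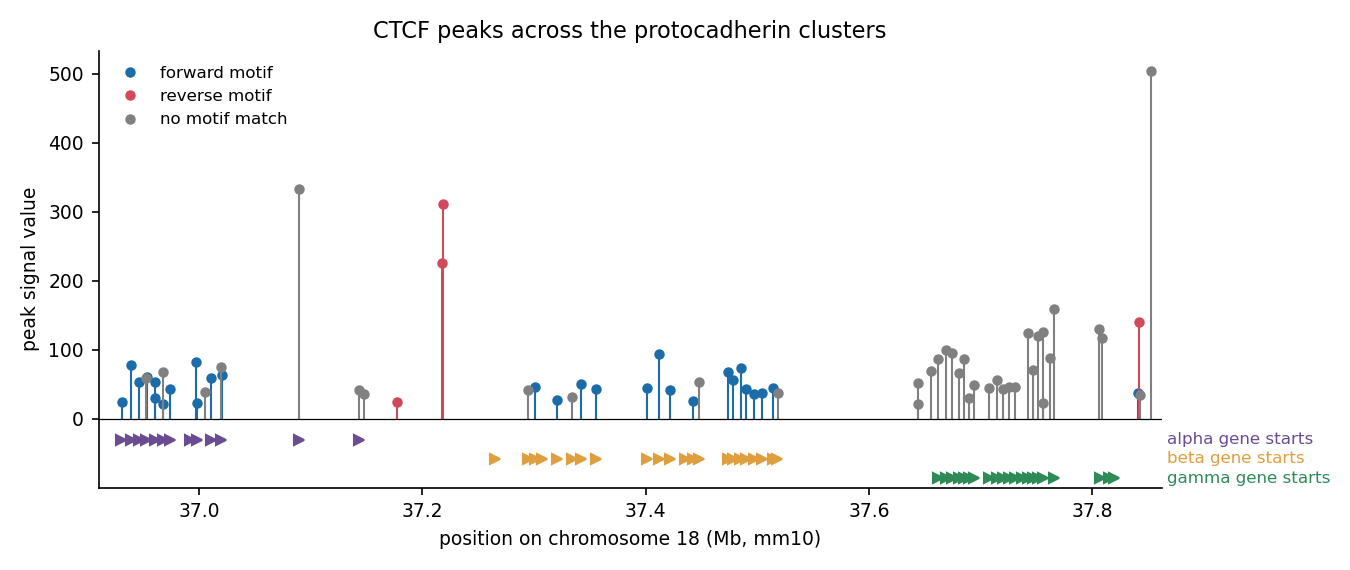
Map of the protocadherin region on chromosome 18 (horizontal axis, position in Mb, mm10), with peaks drawn at their signal (vertical axis) and marked by motif strand, and gene starts below. Forward motifs prevail (28 against 4), and the gamma gene starts carry peaks without a motif match at this threshold.

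CTCF motifs have a direction, so the order of neighbouring motif-bearing peaks was compared with shuffled strands. Of 44235 neighbouring pairs, 52.9% pointed the same way (tandem), 23.57% toward each other (convergent) and 23.56% apart (divergent). After shuffling, convergent pairs made up 24.5% to 25.5%, and the observed share was lower (permutation test, two-sided, p = 1e-05, the smallest that 100000 permutations can give). Along a chromosome the convergent and divergent counts can differ by at most 1, so this is a test of tandem against alternating order, not of convergent against divergent pairs. Distances did differ between these. The median was 28.5 kb for convergent, 20.5 kb for tandem and 17.3 kb for divergent pairs, a log2 ratio of divergent to convergent of -0.72 (SD 0.16 over autosomes), shorter on 19 of 19 (exact sign-flip test, p = 3.81e-06). This distance test was chosen after seeing the data.

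Motif sites in repeats were set against the repeat content of flanking sequence. Of the 44255 motif sites, 12691 (28.7%, interval 28.3 to 29.1) lay in soft-masked sequence, mostly interspersed repeats, against 25.4% of flanking bases, higher on 18 of 19 autosomes (mean difference 3.05 points, SD 2.64; exact sign-flip test, two-sided, p = 6.1e-05). The share rose from 5.41% of sites in the strongest 10% of peaks to 55.0% in the weakest. In the stronger 50% of the list it was 16.0%, below the flanks, and the direction was reversed (exact p = 3.81e-06). At a looser motif threshold it was 24.98% against 24.7% (exact p = 0.877; range over 7 alternatives 3.81e-06 to 0.877). Flanking bases measure nearby repeat sequence, not the motif sites available in it. Of 46615 motif sites in the genome at a p of 1e-06, 20310 lay in soft-masked sequence. Of these 40.1% had a peak, against 71.9% of other sites, so motif sites in repeats had a peak less often. Sites with a surrounding 36-mer that recurs in the genome also had a peak less often, a mean of 26.1% over autosomes. Sites with unique 36-mers gave 68.6% at matched motif score. The contrast between repeats and other sites was not tested among unique sites, so recurring sequence may account for part of it.

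Peak density differed by chromosome. The autosomes held a mean of 28.2 peaks per Mb (SD 5.19, n = 19), from 21.5 on chromosome 3 to 41.3 on chromosome 11. The X chromosome held 9.9 per Mb, below every autosome and 0.351 of their mean, and the median signal of its peaks was 88.8, against 69.6 to 83.0 on single autosomes. The Y chromosome held 0 optimal peaks and 1 peak in each replicate's own list.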

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

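The repeat-free density test, the score-matched share test and the highest-score signal test on the X chromosome, and the strand shuffle of motif distances, were chosen only after the result was seen. With 1 group, the design names no biological difference to test, and a lower copy number of X, which depends on the unrecorded sex, is the only biological explanation tested.

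Signal appeared in sequence that the comparisons left out. Of the optimal peaks, 13 lay on 7 unplaced or unlocalised scaffolds. This is a count with no expected value set against it, since these sequences were left out of every comparison. JH584304 held 6 of them, with a highest signal of 316, and the single peak on GL456359 reached 489.

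The X chromosome held 0.351 of the autosomal peak density. Fewer motif sites alone leave part of this open, since X had 0.547 of the autosomal motif sites per Mb but at matched motif score 40.2% of them had a peak, against 58.9% on autosomes, a difference of -18.7 points, and matching on GC content and repeats left -17.0. Repeat sequence without peaks does not account for it, as the ratio was 0.459 outside repeats. Exact copies alone do not either, since sites with unique 36-mers still differed by -11.2 points (57.5% against 68.6%, autosome range 65.7 to 70.5). Copies with a mismatch counted as unique and the read length is not given, so near-identical copies are not excluded. A lower copy number of X in some animals may contribute, but the values differ. Log2 signal at matched score was only -0.08 from the autosome mean, which the bound set beforehand counted against this explanation. That bound ignored that weak peaks drop out of the list. At unique sites of the highest scores (83 on X, 89.2% of them with a peak) the log2 signal difference was -0.58 (SD of autosomes 0.081). The median signal of all X peaks was above that of every autosome (88.8 against 69.6 to 83.0). Unique motif sites per Mb (0.427 of the autosomal mean) and a lower share of them with a peak (0.837) remain as measured differences, sex was not recorded, and the signal scale is not given in the sources used here, so -0.58 cannot be turned into a copy number.

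Convergent neighbouring sites lay farther apart than divergent ones, with a log2 ratio of -0.72. Close pairs alone do not account for it, as pairs more than 10 kb apart gave -0.53, and neither do sites in repeats, since leaving these out gave -0.94. Among sites in repeats only, the ratio was much closer, -0.18 (SD 0.35 over autosomes), with divergent pairs shorter on 15 of 19. Shuffled strands gave a ratio as far from 0 in 0 of 100 shuffles (range -0.083 to 0.087). Spacing linked to loops, in which convergent sites sit at the ends, is a candidate explanation that these lists hold no measurement of.

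Motif sites in repeats had weaker peaks, with a median signal of 54.1 against 178. Weaker motifs do not account for it, since repeat sites had the higher median score (17.8 against 17.5) and the difference at matched score was -30.9 percentile points. Reads lost to exact copies may account for a small part, as sites with unique 36-mers still differed by -27.0 points, and matching GC content as well as score left -28.7. All 36-mers were unique at 73.2% of repeat sites and 94.7% of others. Copies with a mismatch counted as unique, and the read length, which sets this test's reach, is not given in the sources used here.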

How the results depend on the processing

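The distance between motif sites by orientation, the weaker 50% of the peak list (soft-masked share 48.8%) and the imprinted list's protein-coding members against other protein-coding genes were chosen only after the result was seen. The motif share (8 alternatives), promoter share (7), motif signal (6), convergent share (6) and X density ratio (4) kept their direction, and their side of the threshold where tested, under every alternative run. The motif share ran from 38.5% to 83.0% over motif thresholds, and the promoter share was 44.5% with 5 kb promoters (1.85 times random). Replicate matching moved to 86.6% (any overlap), 82.4% (reciprocal overlap), 91.8% (highest 10000 peaks) and 40.3% (whole lists, which add weak peaks). The rank correlation moved to 0.969 (conservative list) and 0.971 (stronger 50%). The promoter signal difference was -1.26 with 5 kb promoters, and the soft-masked share 16.0% in the stronger 50%, reversed, and 24.98% at a motif threshold of 1e-04. Lists past the threshold numbered 2 in the stronger 50%, where fewer genes have a peak, 6 with 5 kb promoters and 6 with outermost starts. They numbered 5 with GC matching and 7 with the imprinted list against protein-coding genes. The number was 10 with the conservative list, 11 with 500 bp promoters, 13 without replicate 1 and 8 without replicate 2. Loci above the 95th percentile ranged from 3 to 4 when a replicate was left out, and numbered 4 in the conservative list, where the Peg3 domain entered (as without replicate 2), and 6 in the stronger 50%, with H19-Igf2, Xist-Tsix and HoxA entering and Bdnf and Dlk1-Meg3 leaving. In the stronger 50%, shares reversed against other genes for beta protocadherins (4.55%), dopaminergic (25%), GABAergic (22.2%), serotonergic (23.1%), astrocyte (21.4%) and meninges (25%) genes. Other genes stood at 23.1% there, so apart from beta protocadherins these reversals were small. With 5 kb promoters, where other genes stood at 61.3%, they reversed for Hox (64.1%), midbrain (85.7%, adjusted exact p = 0.0279), dopaminergic (70.0%), GABAergic (61.1%), glutamatergic (73.3%), serotonergic (69.2%), oligodendrocyte (66.7%), meninges (83.3%) and muscle (66.7%) genes. The midbrain list's adjusted p ranged from 0.0279 to 1 over its alternatives. With 500 bp promoters they reversed for GABAergic (33.3%) and progenitor (18.75%) genes, with outermost starts for progenitors (18.75%), and with GC matching for GABAergic (percentile 21.7) and progenitor (20.9) genes. With the conservative list they reversed for progenitor (37.5%) and astrocyte (35.7%) genes. Leaving out a replicate gave GABAergic 38.9% to 44.4%, progenitor 43.75% to 43.75% and astrocyte 35.7% to 64.3%, reversed against other genes without replicate 1 for all 3 and without replicate 2 for progenitors. The progenitor count stayed at 7 of 16, and only the share of other genes moved. That share was 43.4% in the main setting, 44.0% without replicate 1 and 44.1% without replicate 2. Of these list reversals, only that of the midbrain list passed the test. Where no construction is named, the cause was not tested. Unknown read depth limits every statement on weak peaks.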

Other observations

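The test of promoter location by motif was chosen only after the result was seen. Peaks without a motif lay more often at promoters, 8094 of 24335 (33.3%, interval 32.7 to 33.9), than peaks with one, 6379 of 44255 (14.4%, interval 14.1 to 14.7). The difference of -18.7 points (SD 2.07 over autosomes) held on 19 of 19 autosomes (exact sign-flip test, two-sided, p = 3.81e-06). Members of the called lists show both kinds. Counting the strongest promoter peak of each gene, the 18 gamma protocadherin genes and the endothelial genes Vwf and Abcc9 lacked the motif at a p of 1e-05 (5 of the 18 had it at 1e-04), 23 of 56 ribosomal protein genes with a promoter peak had it, and 5 of the 7 Hox genes had it.

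Across the genome, 46615 motif sites were found at a per-position p of 1e-06, and 58.0% of them had a peak summit within 100 bp. The share was 28.1% in the weakest 10% of motif scores and 91.3% in the strongest. Sites in soft-masked repeats had a peak in 40.1% of cases and other sites in 71.9%. That contrast was not tested among sites with unique 36-mers. Sites without unique 36-mers had a peak in a mean of 26.1% of cases over autosomes.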
